A study of Mus musculus with 4 samples.

How the data were processed

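The series measured OTX2 binding by CUT&RUN with an anti-HA antibody (diluted 1:100) or control IgG on 500000 cells per sample, in mouse cell lines whose OTX2 carries an HA tag, per the labels' protocols. EpiSCs were kept in 20 ng/ml Activin A, 12.5 ng/ml FGF2 and 175 nM NVP. Live DE cells were sorted, per the labels' protocols. The samples are 4 PS libraries, 3 with anti-HA and 1 with IgG. The anti-HA libraries come from separately named clones. The submitters' processing notes name the mm10 genome build and the tools Bowtie2 2.3.5.1, SAMtools 1.14, Picard 2.26.10, bedtools 2.30 and MACS2 2.2.6, without their order or settings. The peak threshold, the use of the IgG library and the way replicates and stages were combined are not given in the sources used here.

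The authors deposited 4 region lists with 3 columns each, chromosome, start and end, with no header and no height, score or value per library. Each list holds regions bound in the stages its name gives, and the lists share 0 bases. No value per library was used, so nothing could be averaged, depth per library is unknown, and no comparison of anti-HA with IgG was possible. Regions under 50 bp occur only in the lists shared by 2 stages, so widths there partly depend on how regions were matched between stages. EPI is written as in the list names, whose label does not spell it out. Starts were converted to count from 1, and 2 DE only regions on an unplaced scaffold were left out where genes were used.

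Genes came from a RefSeq table of the same assembly (GRCm38, which is mm10), with 21887 protein-coding genes placed on chromosomes. All 206 symbols of the fixed lists matched. The table holds neither strand nor sequence. The planned tests on DNA motifs, which need sequence, were therefore not run, and the planned distance to transcription start sites was replaced by distance to either end of a gene. A region was assigned to the gene whose span holds its midpoint (the shortest if several) or else to the gene with the nearest end within 100 kb. With this rule 87.3% of PS only, 87.4% of PS and DE, 87.4% of DE only and 88.4% of EPI and PS regions were assigned, against 70.6% of 540589 random positions. Positions were drawn between the outermost genes of each chromosome.

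Before the data were examined, 13 gene lists, the tests and the rule for named genes were fixed. The lists are definitive endoderm, primitive streak, epiblast and pluripotency, anterior endoderm and foregut, posterior endoderm and hindgut, WNT, NODAL and activin, and BMP pathways, mesoderm, neurectoderm, extraembryonic endoderm, and housekeeping and lymphocyte controls. Genes named are, per region list, the 8 with the most assigned regions, up to 4 members per fixed list with the most regions, and Otx2. Some genes that this rule names are not reported here. The coordinates given are those of the assigned region closest to the gene. Regions at list members were counted and compared with 10000 random gene lists matched on territory length in 20 bins, by a two-sided permutation test. Shares of regions were compared between lists by Fisher's exact test, two-sided. Gene-end shares were also compared with 10 random windows per region of the same chromosome and width. Proximity to PS and DE regions was compared with random positions matched on chromosome and on distance class to gene ends (up to 1, 10 or 100 kb, or more). Counts were simulated by 1000 binomial draws at the rates of those positions, which treat regions as independent. Median widths were compared by permutation tests with 100000 resamples, two-sided. P-values of the planned comparisons were adjusted by Benjamini-Hochberg within each family, with 52 list tests in one family, and the threshold was 0.05. Single tests of explanations were not adjusted. Regions are not biological replicates, and regions near 1 gene are not independent, so Fisher p-values are too small. Shares have 95% Wilson intervals, which cover counting error only.

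The gene list test was tested on simulated regions drawn over the territories of 21880 genes, with 100 simulated lists of 18 genes per setting. With no excess planted, 0% to 3% of lists were called. With a 3-fold excess, 25% were called at the length of PS only, 85% at that of PS and DE, 100% at that of DE only and 11% at that of EPI and PS. With a 6-fold excess these were 84%, 100%, 100% and 34%. Simulated regions were independent and calls used an unadjusted permutation p under 0.05. Clustering of real regions and the adjustment of real p-values are not covered, so these rates are likely too high for the real tests. Width tests called 2% of 100 draws with no shift and 94% with a shift of 8 bp. The assignment rule gave 0 mismatches at 2000 positions against a direct search.

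Alternatives were merged regions (within 500 bp), regions of at least 150 bp, regions at least as wide as their list's median, overlap of 50%, a gene-end window of 2.5 kb, any base in place of the midpoint, assignment within 50 kb or 1 Mb, counting members or genes once, an exact binomial test on territory, and distances of 10 and 200 kb for proximity. Alternatives chosen after seeing the data were assignment to the nearest gene end inside a gene or not, merged regions in the gene list tests, lists without their member with the most regions, lists without members of other lists, and regions at gene ends left out. Tests of explanations used Mantel-Haenszel odds ratios over 5 classes of gene density and 2000 bootstrap draws over genes. Symbol families were also scanned after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.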

Results

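CUT&RUN was used to locate the transcription factor OTX2 on the genome of mouse epiblast stem cells (EpiSCs) and of cells on the way to definitive endoderm (DE). In CUT&RUN, an antibody guides a nuclease to the protein on chromatin, and the DNA released around it is sequenced. The antibody recognised an HA tag carried by OTX2 in edited cell lines of a BL6/129 hybrid background. The sample titles carry the name OTX2-dTAG. Cells passed through a primitive streak (PS) stage after 16 h in 40 ng/ml Activin A and 3 uM CHIR, a WNT pathway activator. A further 24 h in 100 ng/ml Activin A and 100 nM LDN, a BMP receptor inhibitor, gave DE cells. The 4 libraries described here are PS libraries, 3 with the anti-HA antibody, from 3 clones, and 1 with control IgG, from 1 of those clones. EpiSC and DE libraries were not analysed here. The values are 4 lists of genomic regions bound in PS alone, in PS and DE, in DE alone, or in a stage written EPI together with PS, each without a height or a value per library. Depth per library is therefore unknown, no spread between replicates can be given, and the tests below compare regions or genes and not biological replicates.

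Most OTX2 regions of these lists belonged to DE. The DE only list held 31445 regions, 19.2 times the 1634 regions of PS only and 5.11 times the 6157 regions of PS and DE. The EPI and PS list held 379 regions. Of the 8170 PS regions in the 3 lists that include PS, 75.4% were shared with DE (95% Wilson interval 74.4 to 76.3), 20.0% were in PS alone (19.1 to 20.9) and 4.64% were shared with EPI (4.2 to 5.1). Of the 37602 DE regions in the 2 lists that include DE, 16.4% (16.0 to 16.8) were shared with PS. Regions bound in EPI alone, in EPI and DE, or in all 3 stages were not analysed here, so these shares hold for the 4 lists only, and the intervals cover counting error only. No test was run on the list lengths, which also move with depth and peak calling.

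Regions bound in both PS and DE were more numerous at genes of the endoderm and streak lists than at matched random genes, although these 37 genes held only 1.11% of the assigned regions. The 18 definitive endoderm genes held 44 of them, 8.55 times the 5.14 of matched random gene lists, and 13 of the 18 genes had at least 1 region. Foxa2, a forkhead factor of the endoderm, Lhx1, a LIM homeobox factor, and Cxcr4, a chemokine receptor used as a surface marker of endoderm, held 6 regions each, and the T-box factor gene Eomes held 5. The 22 primitive streak genes held 31 regions (7.30-fold), in 14 genes, among them 4 at Gsc, a homeobox gene of the anterior streak, and 3 at Cyp26a1, which encodes a retinoic acid degrading enzyme. The 19 anterior endoderm and foregut genes held 33 regions (5.73-fold), in 15 genes. Each of these 3 lists had an adjusted permutation p of 0.00104, which comes from the smallest p the random lists can give, 2.00e-04.

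Genes of the WNT and BMP pathways also held more PS and DE regions than random lists. The 27 WNT pathway genes held 38 regions, 3.72-fold, with 20 genes hit. Examples were 4 regions at Sfrp1 and 3 at Frzb, which encode secreted WNT antagonists, and 3 each at the receptor genes Fzd8 and Fzd10. The 16 BMP pathway genes held 26 regions, 4.04-fold, with 8 genes hit, including 6 at Smad1, a transducer of BMP signals, and 4 each at the ligand genes Bmp2 and Bmp7. The adjusted permutation p was 0.00104 for both. The 16 posterior endoderm and hindgut genes held 9 regions (4.19-fold, adjusted permutation p = 0.0243) and the 21 epiblast and pluripotency genes 17 (2.59-fold, adjusted permutation p = 0.0439). The NODAL and activin list, with 3 regions at Lefty1 and 2 at Cer1, held 11 regions (2.52-fold, adjusted permutation p = 0.151). The mesoderm (1.90-fold), neurectoderm (1.82-fold), extraembryonic endoderm (1.33-fold), housekeeping (3.09-fold) and lymphocyte (1.07-fold) lists did not pass 0.05 either.

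The fixed lists overlap, and 20 of the 22 streak genes are on another list. With members of a single list only, the definitive endoderm list had 7.12-fold in the PS and DE regions (adjusted permutation p = 0.0026), while the BMP list shares no gene with another and is not tested by this setting. The anterior list then had 2.33-fold (adjusted permutation p = 0.585), the WNT list 2.81-fold (adjusted permutation p = 0.0957) and the epiblast list 2.71-fold (adjusted permutation p = 0.202). The streak list was left with 2 genes and 1 region, and the posterior list with 10 genes and 0 regions. Without its member with the most regions, the posterior list had 3.04-fold and the epiblast list 2.17-fold, both with an adjusted permutation p of 0.213. The random lists kept their own top member in this setting, which lowers folds by construction, so dependence on 1 gene is not shown. Counting members with a region in place of regions gave 1.92-fold for the BMP list (adjusted permutation p = 0.167), 2.45-fold for the posterior list (adjusted permutation p = 0.28) and 2.67-fold for the NODAL and activin list, which then passed (adjusted permutation p = 0.0331).

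**Figure D1:**
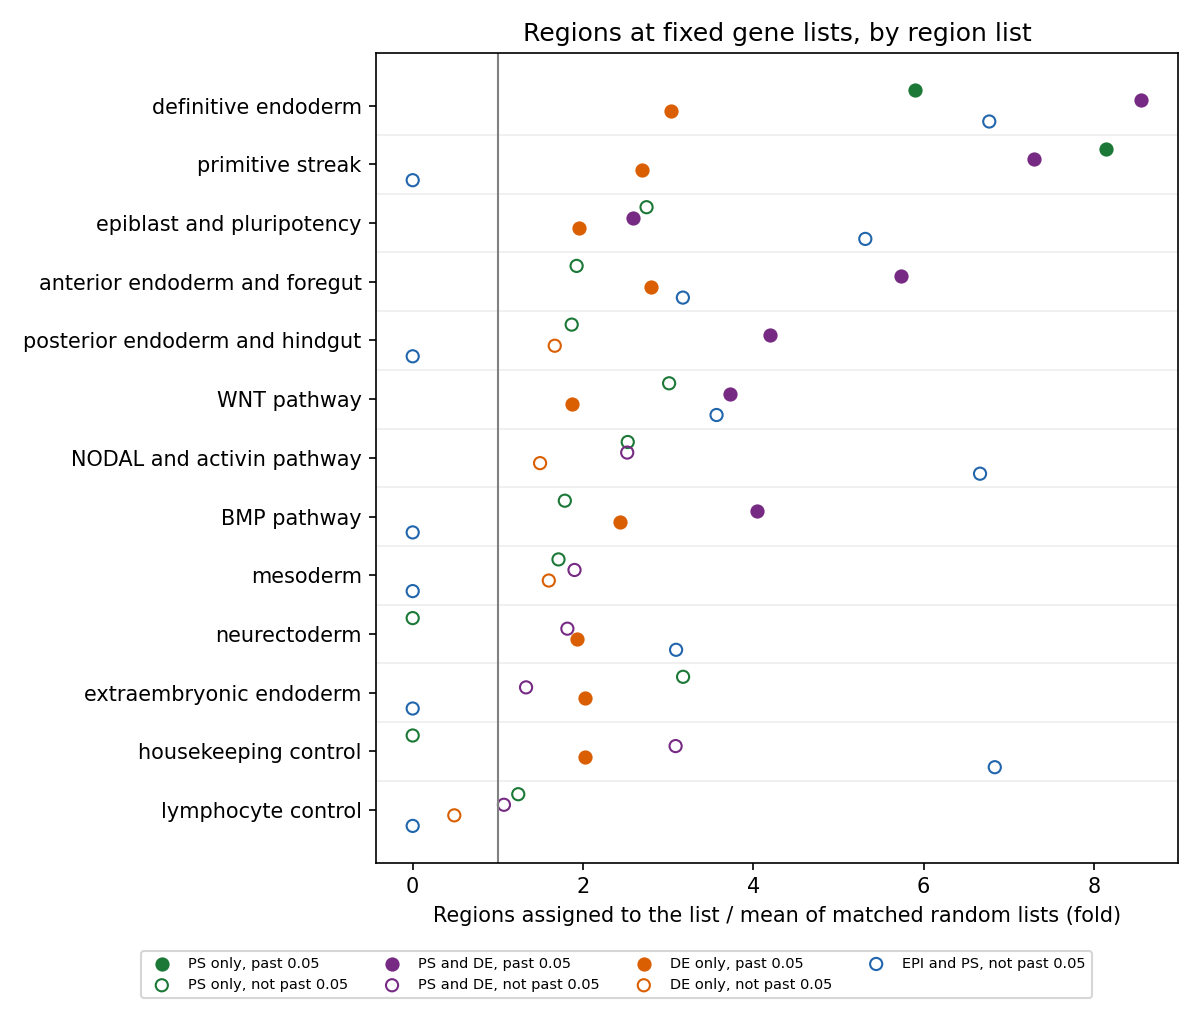
Each point is 1 fixed gene list in 1 region list, and the horizontal axis gives the number of regions assigned to the list divided by the mean of 10000 random gene lists matched on territory (fold, with a grey line at 1). Filled points passed an adjusted permutation p of 0.05 and open points did not, and the PS and DE points reach 8.55 for definitive endoderm and 7.30 for primitive streak.

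PS only regions showed the streak and endoderm lists as well. The streak genes held 9 of them against 1.11 in random lists (8.14-fold, adjusted permutation p = 0.00104), with 2 at Nodal, the ligand that drives streak and endoderm formation, and 1 each at Axin2, Cyp26a1 and Dkk1. The definitive endoderm genes held 8 (5.90-fold, adjusted permutation p = 0.00662), with 2 at Gata6 and 1 each at Cxcr4, Eomes and Foxa2. With members of a single list only, neither passed: the endoderm list had 4.69-fold (adjusted permutation p = 0.216) and the streak list had 0 regions at its remaining 2 genes. Among regions at least as wide as the list's median, the endoderm list had 4.68-fold (adjusted permutation p = 0.16). The WNT list had 8 regions (3.01-fold, adjusted permutation p = 0.0722), with 2 each at Tcf7l2 and Wnt5b, and among the wider regions 5.23-fold (adjusted permutation p = 0.0078). It also passed with assignment within 50 kb (3.40-fold, adjusted permutation p = 0.0404) and with the nearest gene end (3.65-fold, adjusted permutation p = 0.0173). It did not pass within 1 Mb (2.70-fold, adjusted permutation p = 0.0832) or with members counted (2.63-fold, adjusted permutation p = 0.137). The other 10 lists did not pass, and the neurectoderm and housekeeping lists held 0 regions. The gene with the most PS only regions was Camk1d, with 5, followed by Igsf21, Ntn1, Prkag2, Rbfox1, Rora and Tenm2 with 4 each.

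DE only regions were spread over 10968 of the 21887 protein-coding genes, against 3564 genes for PS and DE and 1226 for PS only. They passed the test at 9 lists. The definitive endoderm genes held 77 (3.03-fold), the anterior endoderm genes 80 (2.80-fold), the streak genes 57 (2.69-fold) and the BMP genes 75 (2.44-fold), each with an adjusted permutation p of 0.00104. Foxa2 held 12 of these regions, Gata6 11 and Bmp2 12. The WNT list had 93 regions (1.87-fold, adjusted permutation p = 0.0078), with 10 at Lef1 and 9 at Dkk1, a secreted WNT antagonist. The epiblast list had 64 (1.95-fold, adjusted permutation p = 0.012), the neurectoderm list 58 (1.94-fold, adjusted permutation p = 0.0186), with 10 at Irx3, and the extraembryonic endoderm list 46 (2.02-fold, adjusted permutation p = 0.0266). The housekeeping control also passed, with 20 regions (2.02-fold, adjusted permutation p = 0.0439), and with regions at gene ends left out it had 1.39-fold (adjusted permutation p = 0.67). Without the member with the most regions, the epiblast (1.78-fold), neurectoderm (1.73-fold), extraembryonic (1.76-fold) and housekeeping (1.86-fold) lists no longer passed 0.05. Random lists kept their own top member, so this setting lowers folds by construction. These losses do not show that the calls rested on 1 gene. With only members of a single list, the endoderm list (2.96-fold, adjusted permutation p = 0.0026) passed, as did the BMP list, from which this setting removes no gene. The anterior list then had 1.91-fold (adjusted permutation p = 0.337), the WNT list 1.61-fold (adjusted permutation p = 0.294) and the streak list, with 2 genes left, 1.54-fold (adjusted permutation p = 1), and the other 4 lists did not pass either. Among those 4, the housekeeping list also loses no gene in this setting. Counting members with a region, the anterior list had 1.35-fold (adjusted permutation p = 0.227) and the BMP list 1.42-fold (adjusted permutation p = 0.0728). The housekeeping control passed in that setting, with 15 of its 22 genes (2.13-fold, adjusted permutation p = 0.00693). That fold was above those of the endoderm (1.58-fold) and streak (1.82-fold) lists, but a ceiling fixed this order. Matched random lists averaged 10.2 of 18 genes with a region for endoderm and 10.4 of 22 for streak, against 7.04 of 22 for the control. The endoderm and streak folds could not reach that of the control even with every member hit. The BMP list, with 15 of its 16 genes, was also near its ceiling. The lymphocyte control had 7 regions (0.489-fold, adjusted permutation p = 0.285).

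Direct comparison of region lists asked whether these genes took a larger share of one list than of another. Definitive endoderm genes took 0.817% of assigned PS and DE regions and 0.280% of assigned DE only regions, a ratio of 2.92 (adjusted Fisher's exact p = 1.2e-06). The ratio was 2.78 for streak genes (adjusted Fisher's exact p = 1.05e-04), 2.11 for anterior endoderm genes (adjusted Fisher's exact p = 0.00252), 2.09 for WNT genes (adjusted Fisher's exact p = 0.00137) and 1.77 for BMP genes (adjusted Fisher's exact p = 0.0388). The other 8 lists did not pass. With each gene counted once, the ratio was 2.5 for endoderm (adjusted Fisher's exact p = 0.0707), 2.27 for streak (adjusted Fisher's exact p = 0.0787) and 1.64 for BMP genes (adjusted Fisher's exact p = 0.612), no longer past 0.05. By the same measure, anterior endoderm genes (3.08, adjusted Fisher's exact p = 0.0317) and WNT genes (2.37, adjusted Fisher's exact p = 0.034) still passed. That measure is close to its ceiling in DE only, where 16 of the 18 endoderm and 19 of the 22 streak genes have a region, so its ratios partly follow list length. Assignment within 50 kb also ended the call for BMP genes (adjusted Fisher's exact p = 0.394). Between DE only and PS only, 0 of the 13 lists differed. The lowest p was that of the streak genes, 0.207% against 0.631% (Fisher's exact p = 0.00498, adjusted 0.0648), which passed with assignment within 50 kb (adjusted Fisher's exact p = 0.0186), with the nearest gene end (adjusted Fisher's exact p = 0.00571) and without gene-end regions (adjusted Fisher's exact p = 0.0452). With each gene counted once, under the same ceiling, the DE only share was 0.256 times that of PS only for endoderm and 0.265 times for streak genes (adjusted Fisher's exact p = 0.0383 for both). Regions near 1 gene are not independent, so these Fisher p-values are too small.

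Single loci held regions of several lists. At Foxa2 (chromosome 2, 148042877 to 148046969, mm10) the PS only region nearest the gene lay at 148041583 to 148041739, 1.22 kb outside it, and the nearest PS and DE region lay inside, at 148046349 to 148046447. At Eomes (chromosome 9, 118478186 to 118486132) a PS and DE region at 118486473 to 118486651 lay 0.43 kb from the gene and a PS only region at 118489082 to 118489181 lay 3.00 kb from it. At Lhx1 (chromosome 11, 84517975 to 84525534) a PS and DE region lay 0.532 kb outside the gene, at 84526033 to 84526100, and at Gsc (chromosome 12, 104471209 to 104473236) one lay 0.323 kb outside, at 104473360 to 104473759. DE only regions lay nearer, across a gene end, at Lhx1 (84525482 to 84525783) and at Eomes (118478005 to 118478210). The nearest DE only region lay 1.67 kb from Foxa2 and 4.51 kb from Gsc, farther than the PS and DE region. Otx2 itself (chromosome 14, 48656781 to 48667644) had 10 DE only regions, 1 PS and DE region at 48708094 to 48708364, 40.6 kb from the gene, and 0 in the other lists. Its territory of 159 kb would hold 2.29 DE only regions at the mean rate over gene territories. Exons, introns and UTRs were not told apart, because the annotation used here gives gene spans only.

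**Figure D2:**
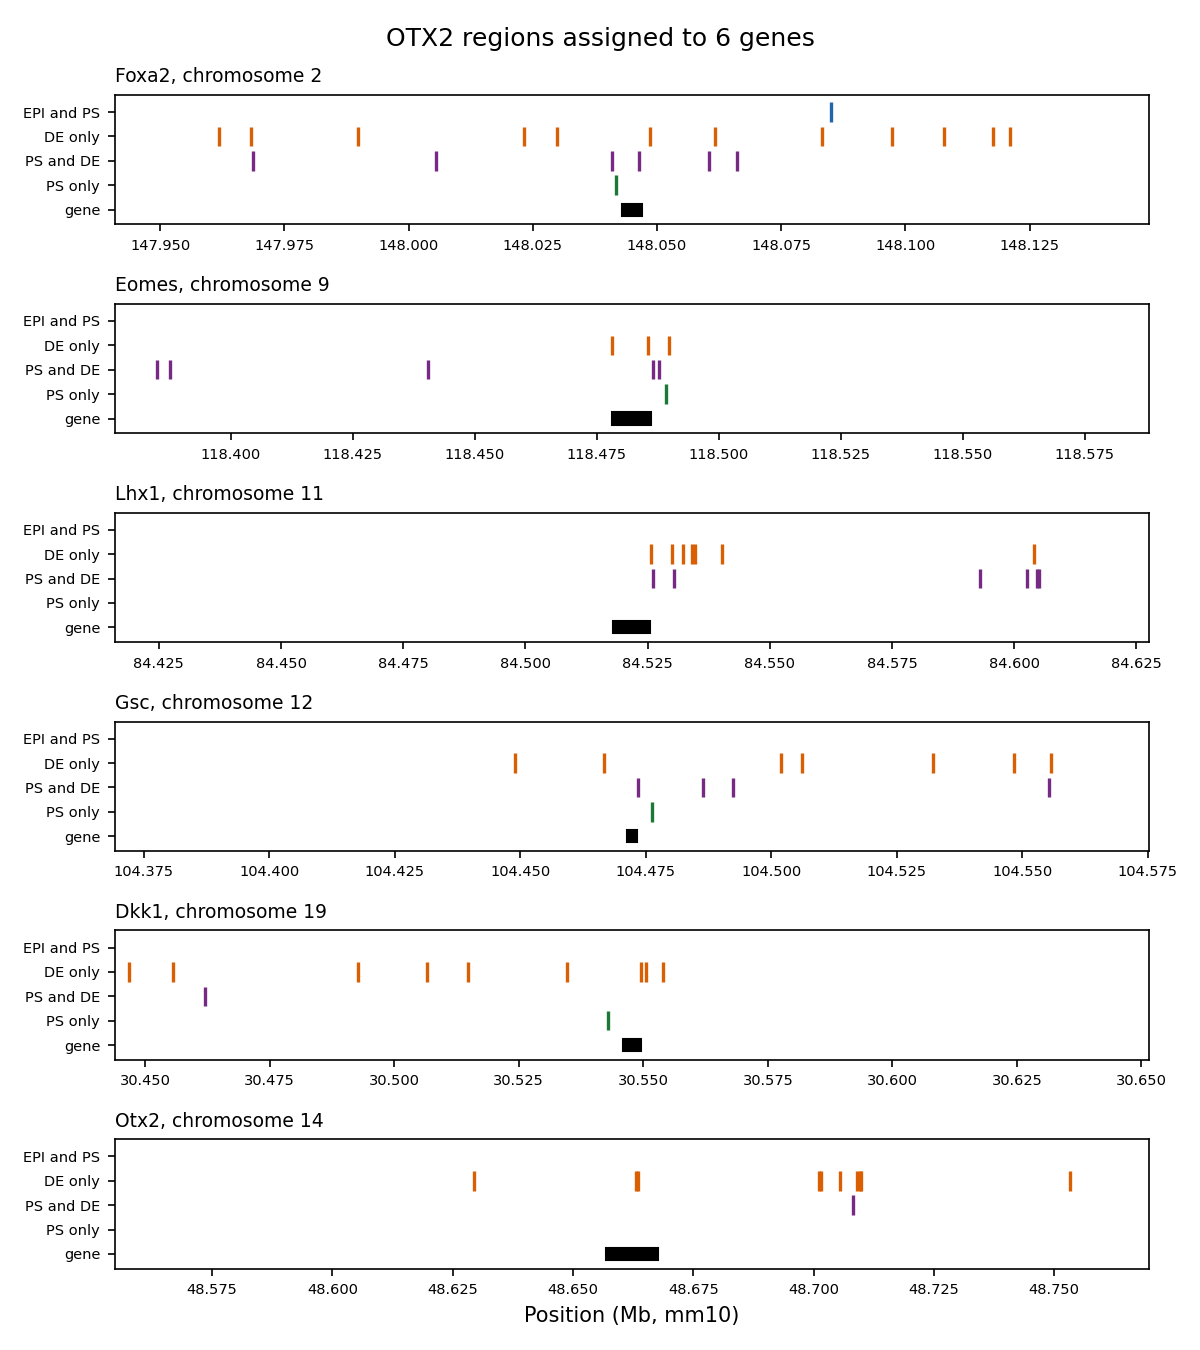
The 6 panels show, on the horizontal axis, position in Mb (mm10) around Foxa2, Eomes, Lhx1, Gsc, Dkk1 and Otx2, with the gene span as a black bar and each assigned region as a vertical tick in the line of its region list. Otx2 has 10 DE only ticks and 1 PS and DE tick, and Lhx1 has 7 and 6.

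The EPI and PS regions passed the test at 0 of the 13 lists. Of the list genes, they held 1 region each at Pou5f1 and Utf1, of the pluripotency list, at Foxa2 and Trh, and at Lefty1, Skil, Fzd5, Lgr5, Nes and Rps9. With 335 assigned regions, simulated lists with a planted 6-fold excess were called in 34% of draws, at an unadjusted permutation p under 0.05. Smaller excesses were therefore mostly not detectable at this list length, where the real tests used adjusted p-values. Slfn14 held 3 of these regions, and 7 further genes named by the same rule, among them Bcar3 and Deptor, held 2 each.

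Regions near gene ends were most frequent in DE only. A midpoint within 1 kb of either end of a protein-coding gene was found for 14.2% of DE only regions (95% Wilson interval 13.8 to 14.6), 10.6% of PS and DE (9.81 to 11.3), 8.71% of EPI and PS (6.27 to 12.0) and 7.77% of PS only (6.57 to 9.17). These were 4.56, 3.36, 2.82 and 2.43 times the shares of random windows of the same chromosome and width. The PS only share was 0.547 times that of DE only and the PS and DE share 0.743 times that of DE only, both with an adjusted Fisher's exact p of 1.57e-14. PS only also lay below PS and DE (0.736 times, adjusted Fisher's exact p = 0.00138), and DE only above EPI and PS (1.63 times, adjusted Fisher's exact p = 0.00264), but with a window of 2.5 kb these ratios were 0.878 (adjusted Fisher's exact p = 0.0835) and 1.10 (adjusted Fisher's exact p = 0.404). The annotation used here gives no strand, so the start of a gene could not be told from its end.

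**Figure D3:**
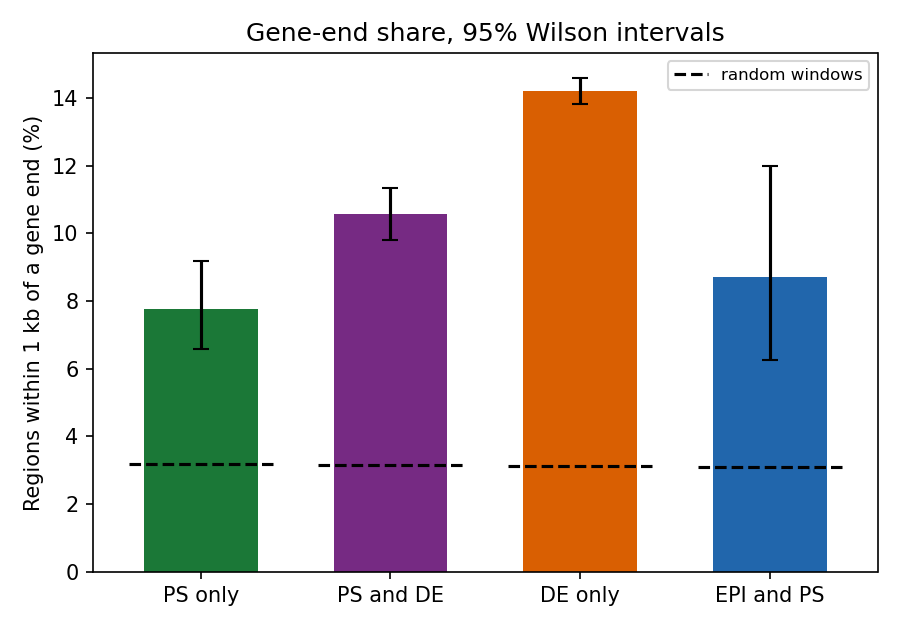
Bars give the percentage of regions whose midpoint lay within 1 kb of a protein-coding gene end, for the 4 region lists, with 95% Wilson intervals as error bars and the share of random windows as dashed lines. The bars run from 7.77% in PS only to 14.2% in DE only.

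Regions of the other 3 lists lay beside PS and DE regions more often than random positions did. Of PS only regions, 41.4% lay within 50 kb of a PS and DE region, against 20.8% of random positions matched on chromosome and distance to gene ends. The shares were 33.4% against 20.7% for DE only and 34.6% against 21.6% for EPI and PS. All 3 had a p of 0.002 from the binomial draws, the smallest that 1000 draws can give. The draws treat regions as independent, so clustering of regions is not covered by this p. The PS only share was 1.24 times that of DE only (adjusted Fisher's exact p = 2.36e-10) and 1.2 times that of EPI and PS (adjusted Fisher's exact p = 0.022), the latter 1.05 times within 200 kb (adjusted Fisher's exact p = 0.232). Some neighbours from different lists lay under 1 kb apart. At Lhx1 a DE only region ended at 84530212 and a PS and DE region began at 84530392. Whether such pairs are pieces of a single element was not tested.

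Gene spans held 44.4% of PS only, 46.4% of PS and DE, 47.5% of DE only and 40.6% of EPI and PS midpoints, and 38.1% of random positions. The X chromosome held 2.02%, 1.75%, 2.25% and 1.32% of these lists, against 4.41% of protein-coding genes, and 0 of the 6 pairs of lists differed (lowest adjusted Fisher's exact p = 0.0877; 1 pair had an unadjusted exact p under 0.05, 0.0146). Among regions at least as wide as their list's median, the PS and DE share was 0.633 times that of DE only (adjusted Fisher's exact p = 0.0135). Median widths were 115 bp, 123 bp, 119 bp and 110 bp in the same order. PS and DE regions were wider by 8 bp than PS only (adjusted permutation p = 0.00288), by 4 bp than DE only and by 13 bp than EPI and PS (adjusted permutation p = 0.00334 for both). Among regions of at least 150 bp the last 2 differences were 0.5 bp (adjusted permutation p = 0.768) and 10 bp (adjusted permutation p = 0.266), and with neighbouring regions merged that with DE only was 3 bp (adjusted permutation p = 0.0637). Regions under 50 bp were found only in the lists shared by 2 stages, 186 in PS and DE and 14 in EPI and PS. The narrowest region was 77 bp in PS only, 62 bp in DE only, 2 bp in PS and DE and 5 bp in EPI and PS. The width tests do not allow for these different lower limits.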

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

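The comparison restricted to the wider regions of both lists was used as a test of an explanation only after the planned narrow against wide comparison had been seen. The other tests of explanations were fixed before their results were seen. The written rules for endoderm and streak genes set no bound on the bootstrap interval. The items below stand out because region lists differed by a test of the difference itself.

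DE only regions lay at gene ends more often than PS only regions, whose share was 0.547 times as high (adjusted Fisher's exact p = 1.57e-14). Gene density was argued against as the whole cause, since among regions with similar numbers of gene ends within 100 kb, the Mantel-Haenszel odds ratio was 2.11 (95% interval 1.74 to 2.55), against 1.96 unadjusted. The narrower regions of both lists do not make the difference, since among regions at least as wide as their list's median the DE only share was 2.60 times that of PS only (14.0% against 5.37%, Fisher's exact p = 1.09e-14). Weak regions in the longer list stay open: narrow DE only regions had 1.03 times the gene-end share of wide ones (Fisher's exact p = 0.272), and width is only a stand-in for strength, which the lists do not give. Signal at the open ends of ubiquitously expressed genes also stays open. Such genes were picked by symbol family alone (Mrpl, Mrps, Psm, Nduf, Eif, Polr, Snrp, Cct, Atp5 and Cox). Neither their expression nor their openness was measured here. Of these 309 genes, 30.4% held a DE only region at an end, against 20.7% of 21372 others (Fisher's exact p = 7.07e-05). That is 1.47 times, under the 1.5 set beforehand. The same ratio was 1.53 in PS and DE (Fisher's exact p = 0.102) and 1.03 in PS only, where 2 such genes are too few to compare. Stage, depth and peak calling cannot be told apart here.

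Endoderm and streak genes took a larger share of PS and DE than of DE only regions, with ratios of 2.92 (adjusted Fisher's exact p = 1.2e-06) and 2.78 (adjusted Fisher's exact p = 1.05e-04), or 2.5 (adjusted Fisher's exact p = 0.0707) and 2.27 (adjusted Fisher's exact p = 0.0787) with each gene counted once. For the 37 genes of both lists together the ratio was 2.62 (bootstrap over genes 1.87 to 3.59). Dilution of DE only by narrow regions was argued against, since the ratio was 2.94 (1.96 to 4.39) among wider regions. Without gene-end regions the ratio was 2.34 (1.64 to 3.27). Leaving them out took the assigned DE only regions from 27471 to 23005, too small a loss for dilution alone to bring the ratio below 1.5. That test could therefore not have pointed to dilution by gene-end regions. A few loci with many regions stay open as a cause. Without Cxcr4, Foxa2, Lhx1, Eomes and Gsc the ratio was 2.05 (1.34 to 3.20), an interval that includes 1.5. Of the 37 genes, these had the most PS and DE regions, so leaving them out lowers the ratio in part by construction. The fall therefore does not show that a few loci were the cause. The ratio alone met the rule written beforehand against this cause, which set no bound on the interval. Stage was not separated from calling strength, regions found in both stages could be the stronger ones, and no biological explanation was tested.

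The PS only gene-end share was 0.736 times that of PS and DE, the PS and DE share was 0.743 times that of DE only, and the DE only share was 1.63 times that of EPI and PS. With a 2.5 kb window the first and last of these were 0.878 and 1.10, neither past 0.05. The share of regions within 50 kb of a PS and DE region was 1.24 times as high in PS only as in DE only and 1.2 times as high as in EPI and PS, the latter 1.05 times and not past 0.05 within 200 kb. Between PS and DE and DE only, the ratio of shares was 2.11 for anterior endoderm genes, 2.09 for WNT genes and 1.77 for BMP genes, the last not past 0.05 with assignment within 50 kb (adjusted Fisher's exact p = 0.394) or with each gene counted once (adjusted Fisher's exact p = 0.612).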

How the results depend on the processing

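Of the 119 planned and added alternatives to the results that answer a comparison, 93 kept their direction and side of the threshold or stayed within 1.5 times the count, and 26 did not. The cause of those changes was not tested, except that fewer regions or genes enter some settings by construction. At 150 bp or wider, 448 PS only, 2162 PS and DE, 10661 DE only and 98 EPI and PS regions were left, and PS and DE exceeded DE only in median width by 0.5 bp and EPI and PS by 10 bp, neither past 0.05. Merging gave -6 bp for PS only against DE only and 12 bp for DE only against EPI and PS, both now past 0.05, and 3 bp for PS and DE against DE only, no longer past it. With a 2.5 kb window the gene-end ratio was 0.878 for PS only against PS and DE and 1.10 for DE only against EPI and PS, neither past 0.05. Within 200 kb the proximity ratio of PS only to EPI and PS was 1.05, no longer past 0.05. The X share of PS and DE was 0.633 times that of DE only among wider regions, now past 0.05.

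Counting members gave 5 lists with more DE only regions, the housekeeping control among them, in place of 9. The binomial test on territory gave 5 lists for PS only, 11 for PS and DE and 2 for EPI and PS, in place of 2, 7 and 0. The 11 include the housekeeping control (5.05-fold, adjusted exact binomial p = 0.00761). In DE only that control had 3.95-fold by this test, against 3.74-fold for the endoderm list. The binomial test assumes an even rate per base, which gave 5.06 DE only regions for the control, against 9.89 in random lists matched on territory. By those matched lists the control had 2.02-fold and the endoderm list 3.03-fold. Of settings chosen after seeing the data, leaving out the top member, while random lists kept theirs, gave 5 lists for DE only. Members of no other list gave 0 for PS only, 2 for PS and DE and 2 for DE only, with BMP, which this setting leaves as it is, in both. There the streak list in PS only and the posterior list in PS and DE fell to a fold of 0. Between DE only and PS only, 1 list differed with assignment within 50 kb, 2 with each gene counted once, 1 with the nearest gene end and 1 without gene-end regions, in place of 0. Between PS and DE and DE only, 2 differed with each gene counted once, in place of 5.

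Among single gene list values, 588 alternatives kept their side of the threshold, 39 lost it, 21 gained it and 2 turned direction. Leaving out each replicate, motif settings and start sites of every transcript were not run, for lack of values per library, sequence or strand. No paired analysis was possible because the lists carry no value per library. Depth is unknown.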

Other observations

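All tests in this part were chosen after the data were seen. A scan of 257 families of protein-coding genes with at least 10 members by symbol, in the PS only, PS and DE and DE only lists (771 tests), gave 1 family with more regions than matched random genes and 19 tests with fewer. Keratin genes (Krt) held 51 DE only regions against 27.3, 1.87-fold (adjusted permutation p = 0.0171), with 7 at Krt80, 6 at Krt7 and 4 at Krt18, the last a partner of Krt8 in simple epithelia. Fewer DE only regions than in random genes lay at olfactory receptors (Olfr, 127 against 608), vomeronasal receptors (Vmn, 69 against 352), cytochrome P450 genes (Cyp, 45 against 110) and the placental prolactin family (Prl, 0 against 26.7), each with an adjusted permutation p of 0.0103. Read placement among related genes was not examined, and neighbouring members are not independent.

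Forkhead and Hox genes carry a letter before their number and were split by the symbol rule. They were regrouped into single families after the first scan had been seen, and the scan was run again. The 44 forkhead genes (Fox) then held 37 PS and DE regions against 14.0, 2.65-fold (adjusted permutation p = 0.0308), with 7 at Foxn3, 6 at Foxa2 and 4 at Foxp4. Their DE only regions numbered 117 against 69.9 (1.67-fold, adjusted permutation p = 0.0971). The 39 Hox genes held 4 PS and DE regions (1.33-fold) and 22 DE only regions (1.2-fold), both with an adjusted permutation p of 1. This regrouping was prompted by knowledge of forkhead genes in the endoderm, and Foxa1, Foxa2 and Foxa3 are also on the definitive endoderm list, so that it is not independent evidence.

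By count alone, Auts2 held the most DE only regions, 46 against 18.3 at the mean rate for its territory of 1271 kb, and shared the highest PS and DE count, 11, with Asic2. Gse1 held 29 DE only regions against 5.44, while Macrod2 held 29 against 30.0. These genes were named by the fixed rule and not tested singly.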
